A study of Mus musculus with 8 samples.

How the data were processed

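RNA from sorted spleen cells was hybridised to Mouse Exon 1.0 ST arrays. Per the labels, B220-positive B cells or B220-negative leukaemia cells were sorted, and the 8 arrays were grouped by their titles into control (3 arrays), DPB B220+ (2 arrays) and B-ALL (3 arrays). The labels do not say which arrays came from separate mice, so p-values measure only the spread between these samples, which may be technical. The genotypes behind the group names are not spelled out in the labels.

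The authors analysed the arrays in Partek Genomics Suite, removed batch effects with ComBat and took genes past a one-way ANOVA with p below 0.05 and 1.5-fold, per the series' design text. The submitters' processing notes name Partek and the genome build mm9. How probes were summarised and their background corrected is not given in the sources used here. No genome of that build was used here, so no coordinates are given, and chromosomes are those of the deposited annotation.

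The value table holds log2 values as deposited by the authors. That the scale is base 2 was read from the values: the differences of group means of 234 control rows had a slope of 0.995 on the log2 ratios of the authors' deposited tables (r = 0.99 across rows). The values have no centring per row. For the 164 named rows the slope was 0.754 and 158 had the same sign, so the value table and the authors' tables appear to have been summarised differently, and values of both are not mixed. Its identifiers end at 6763466 while those of the authors' deposited tables reach 7023132, and rows outside the value table are described from the authors' tables alone. Every value column was used.

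The authors' deposited tables give, per the file headers, a linear ratio and a signed fold of B-ALL over control, p-values of the ANOVA and of its contrast, and an F score with its sums of squares. A signed fold is minus the inverse of the ratio where that is below 1. The F scores and sums of squares that the authors deposited fit 2 and 5 degrees of freedom, that is, the same 8 arrays in 3 groups. The contrast p-values in the authors' deposited tables were recomputed to within 0.00210 on the log10 scale. The largest deposited contrast p-value was 0.00236 and the smallest fold 1.50. Of 4129 rows, 3387 had a gene symbol (3373 genes) and 737, or 17.8%, were annotated as array controls and left out of gene counts. By RefSeq accession 3288 named rows matched a gene of the reference table, 292 of them under another current symbol, and the file's symbol is printed. A date-like form of 2 symbols was restored through the accession where it matched. A value table row was named where its identifier stood in the authors' deposited tables.

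Tests on the value table used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 8 arrays in 1 fit, group as the only term) with Benjamini-Hochberg adjustment at 0.05 over 16380 rows. Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the 12 genes with the largest rise and the 12 with the largest fall past the threshold with no overlap between the arrays of both groups, plus Sfpi1, Spib and Cd19, plus up to 4 members per list. Where a list had no more than 1 member in the value table, its members were taken from the authors' deposited tables, those with the largest folds first, and some further members were named after their values were seen. Immunoglobulin segment genes were counted apart. The 5 named calls in DPB B220+ against control are all that passed the rule.

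The plan to test gene lists with camera was not kept, because most value table rows carry no gene name here. In its place, chosen after the data were seen, a two-sided Fisher's exact test asked whether a list's members in the authors' deposited tables split into increased and decreased unlike all 3373 listed genes, with Benjamini-Hochberg adjustment over the 18 of 20 lists that had a member there. It tests direction among listed genes and says nothing of genes that were not listed. As 2082 of the 3373 listed genes were increased, a wholly increased list needs more members to pass than a wholly decreased one. The test also treats genes as independent, while genes of a list can change together on the same arrays. Its p-values may therefore be too small. Some genes belong to several lists, so the lists are not separate evidence.

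The sample titles carry numbers in 3 consecutive runs. The first run holds 1 array of each group, the next holds 2 control arrays and 1 DPB B220+ array, and the last holds 2 B-ALL arrays. The numbers' meaning is not given in the sources used here. A fit with these runs as a block was planned as an alternative, and its values stand beside the main ones because the deviations of the arrays cancel within runs, as after a correction for them. A fit without the block then counts 5 residual degrees of freedom where 3 remain. As the last run holds only B-ALL arrays, the term of that run takes up both of them. A blocked comparison of B-ALL therefore takes its difference from B-ALL replicate 1 alone. The run error recomputes the contrast p-value of the authors' deposited tables with 3 degrees of freedom and a standard error 2.07 times as large, and a gene passed where p stayed at or below 0.00236, the largest deposited contrast p-value. The limit of 0.05 was used beside it. It assumes that the same correction lies under those tables. The factor is the same for every gene, so the run error keeps the order of the deposited p-values. It acts as a stricter limit on them and holds no measurement of the runs for a gene.

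The fits were tested on simulated data of 16380 rows with 200 changed. For B-ALL against control, with independent arrays the fit without a block recovered 88% of changed rows, and with run effects removed beforehand 92.2% of its calls were false. In that setting the fit with the block had 4.03% false calls and recovered 50% of 2-fold and 100% of 16-fold changes. For DPB B220+ against control, 57.7% of calls without the block were false after run removal, against 7.88% with it, and for B-ALL against DPB B220+ 88.2% against 3.20%. In 50 simulations of unchanged groups after run removal, limma without a block called 81.5, 2185 and 1321 rows on average in DPB B220+ against control, B-ALL against control and B-ALL against DPB B220+. Counts without the block are therefore upper values.

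Alternatives were quantile normalization, median centring, removal of the 4095 rows of lowest mean, trended and robust variances, array weights, fits on 2 groups, the runs as a fixed or random block, 1 row per gene, the methods' ANOVA with and without adjustment, fold minimums, and each array left out. Added after the data were seen were the removal of rows in the identifier range of the array controls, the block at 1.5-fold and an unadjusted p below 0.05, and, for the authors' tables, a fold of at least 2, a contrast p below 0.0005 and the run error at either limit. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.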

Results

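Gene expression was measured on Mouse Exon 1.0 ST arrays in spleen cells sorted from C57BL/6 mice aged 11 to 18 weeks. The 8 arrays fell into 3 groups. The 3 control arrays hold sorted B cells of mice labelled Control DB, and B220, the isoform of CD45 found on B cells, was the marker of the sort. From mice labelled CD19-CreDPB, 2 arrays hold B220-positive B cells and 3 hold B220-negative cells labelled B-ALL, that is, B cell acute lymphoblastic leukaemia. These 3 groups are called control, DPB B220+ and B-ALL below. The series title concerns PU.1 and Spi-B, transcription factors of the ETS family encoded by Sfpi1 and Spib, and their part in pre-B cell transformation and B cell receptor signalling. A table of log2 values held 16380 rows per array, with column medians from 4.11 to 4.18. The authors' deposited tables held 4129 rows on B-ALL against control, 1754 decreased and 2375 increased, and 398 of these rows also stood in the value table. Only 164 rows of the value table could be named, because naming rested on the same identifier standing in the authors' deposited tables. Of these, all 141 with a readable chromosome were on chromosome 1. The number of arrays limits the precision of every value here.

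The genes named by the design were looked up first. Sfpi1 on chromosome 2, the gene of PU.1, was 69.2-fold lower in B-ALL than in control in the authors' deposited table (unadjusted contrast p = 1.4e-08). Spib, the gene of Spi-B, and Cd19, the gene whose Cre insertion the mouse name carries, stood in neither of the authors' deposited tables, so no change of either is given. Ptprc, which encodes CD45 and with it B220, was 109-fold lower in the authors' deposited table (p = 5.13e-07). In the value table Ptprc (row 6762603) averaged 13.05 ± 0.17 (SD, n = 3) in control, 12.98 ± 0.09 (SD, n = 2) in DPB B220+ and 6.29 ± 0.27 (SD, n = 3) in B-ALL cells. B220 was the sort marker, and whether the sort accounts for this gap was not tested. A value for the whole of Sfpi1 also includes exons outside any deleted part, so it checks the label and not the deletion itself.

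Of the B cell receptor signalling genes listed as changed, nearly all were lower in B-ALL than in control cells. In the authors' deposited tables, 15 of the 33 members of this list were decreased, 1 was increased and 17 were not listed. Cr2, complement receptor 2 of the B cell co-receptor, was 153-fold lower in the authors' deposited table, and Blk, a Src family kinase, 23.9-fold lower. Nfatc2, a calcium-regulated transcription factor, was 19.3-fold lower and Card11, the scaffold that passes receptor signals to NF-kB, was 18.9-fold lower in the authors' deposited table. Smaller decreases in the authors' deposited table were those of Btk, 2.50-fold, and Blnk, 2.29-fold, and the 1 increase was that of Cd81, 1.71-fold. Against all 3373 genes listed, of which 1291 were decreased, this lean had an adjusted p of 3.26e-05 by a two-sided Fisher's exact test. With the error recomputed for the runs of sample numbers described under the methods, 8 members passed, all decreased, and the adjusted p was 0.0490, while Card11, Btk and Cd81 did not pass at the limit of 0.00236. At a run-error p below 0.05 all 16 listed members stayed (adjusted p = 2.97e-05). The series title names this pathway, so its direction is not independent evidence.

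Among genes listed as changed, those of mature B cells and of antigen presentation were nearly all lower in B-ALL, and those of precursor B cells were higher. Of 23 genes of follicular and marginal zone B cells, 16 were decreased and 1 was increased in the authors' deposited tables (adjusted p = 1.97e-05, Fisher's exact test), and this held with the run error (adjusted p = 0.0240). Fcer2a, which encodes CD23, was 144-fold lower in the authors' deposited table, Ms4a1, which encodes CD20, 123-fold lower, and Cd40, the receptor of T cell help, 55.2-fold lower. All 11 listed members of the 14 genes of MHC class II presentation were decreased in the authors' deposited table (adjusted p = 9.90e-05, and 0.0495 with the run error). H2-Aa, a class II alpha chain, was 153-fold lower, Ciita, the class II transactivator, 82.8-fold lower, and Cd74, the invariant chain, 44.3-fold lower in the authors' deposited table. In the other direction, 11 of 21 precursor B cell genes were increased and 0 were decreased in the authors' deposited tables (adjusted p = 0.0181). Il7r, a chain of the interleukin-7 receptor, was 24.6-fold higher in the authors' deposited table, and Rag1 and Rag2, which encode the V(D)J recombinase, were 11.2-fold and 9.10-fold higher. Enpep, the BP-1 antigen of early B cells, was 150-fold higher and Myb 13.2-fold higher in the authors' deposited table. The precursor lean did not pass with the run error (adjusted p = 0.218), where 3 members, all increased, remained, and Il7r, Enpep and Myb were not among them. With 3 members left, even a split wholly in 1 direction could not have passed that test. At a run-error p below 0.05 all 11 stayed (adjusted p = 0.0192).

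Among genes listed as changed, those of innate sensing and nearly all of homing were lower, and those of the cell cycle higher, in B-ALL. Toll-like receptor and NF-kB genes had 18 of 24 members decreased and 0 increased in the authors' deposited tables (adjusted p = 5.20e-07, and 0.0495 with the run error). Ly86, the partner of the toll-like protein RP105, was 191-fold lower in the authors' deposited table, Tlr1 154-fold, Tlr7 65.0-fold, Tlr9 57.8-fold and Rel, an NF-kB subunit, 7.43-fold lower. Homing receptors and adhesion genes had 13 of 17 members decreased and 1 increased in the authors' deposited tables (adjusted p = 9.90e-05, and 0.160 with the run error). Gpr183, an oxysterol receptor that positions B cells, was 155-fold lower in the authors' deposited table, Ccr6 139-fold lower and S1pr1, the receptor for exit into blood, 8.56-fold lower, while Cxcr4, which holds precursors in marrow, was 2.19-fold higher there. In the value table Cxcr4 (row 6762024) showed no such rise, with a B-ALL minus control difference of 0.03 ± 0.04 (SE; limma adjusted p = 0.571). It averaged 4.05 in control and 4.08 in B-ALL, below the column medians of 4.11 to 4.18. A row so near background cannot weigh for or against the rise. Rel and Cxcr4 did not pass with the run error at 0.00236. At a run-error p below 0.05, 13 of the 14 listed homing genes stayed (adjusted p = 0.000243). Of 28 cell cycle genes, 23 were increased and 0 were decreased in the authors' deposited table (adjusted p = 9.90e-05), and with the run error 2 passed at 0.00236, Tk1 and Mcm2 (adjusted p = 0.390), while 20 stayed at a run-error p below 0.05 (adjusted p = 0.000243). With 2 genes left at 0.00236, no split of this list could have passed there. Cdk1, the mitotic kinase, was 10.6-fold higher in the authors' deposited table, Ccnb1, its cyclin, 10.4-fold, Tk1, thymidine kinase, 6.16-fold and Mcm2, of the replicative helicase, 4.49-fold higher.

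Lists of transcription factors, cytokine signalling, apoptosis and glycolysis did not pass an adjusted p of 0.05 in the authors' deposited tables. B lineage transcription factors were split, 9 increased and 6 decreased of 23 in the authors' deposited tables (adjusted p = 1.0), with Lef1 24.6-fold higher, Ebf1 1.72-fold higher and Klf2 13.6-fold lower. ETS family factors had 3 increased and 4 decreased of 18 in the authors' deposited tables (adjusted p = 0.564), among them Sfpi1 and, in the other direction, Etv5, 4.15-fold higher. IL-7 receptor and JAK-STAT genes had 5 increased and 7 decreased of 20 in the authors' deposited tables (adjusted p = 0.380). Socs2 and Cish, both feedback inhibitors of cytokine signalling, were 145-fold and 9.96-fold higher in the authors' deposited table, while Stat3 was 2.08-fold and Jak2 1.86-fold lower. Apoptosis and tumour suppressor genes had 6 increased and 0 decreased of 24 in the authors' deposited tables (adjusted p = 0.159), including Cdkn1a, the p21 inhibitor, 29.8-fold higher, and Bcl2l1, the survival factor Bcl-xL, 18.8-fold higher. Glycolysis genes had 3 increased and 3 decreased of 17 in the authors' deposited tables (adjusted p = 0.766). Lef1, Klf2, Socs2 and Jak2 passed with the run error at 0.05 but not at 0.00236.

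Markers of other spleen cells that a B220-negative sort could hold moved in both directions. Of 19 T cell markers, 3 were increased and 5 decreased in the authors' deposited tables (adjusted p = 0.410). Zap70, the kinase of the T cell receptor, was 27.8-fold higher and Lck 4.75-fold higher in the authors' deposited table, while Cd3e, a chain of that receptor, was 4.90-fold lower and Cd4 2.10-fold lower. Macrophage and monocyte markers had 5 of 18 decreased and 0 increased in the authors' deposited tables (adjusted p = 0.0181), with Emr1 7.90-fold lower. The lean of this list did not pass with the run error at 0.00236 (adjusted p = 0.649) and did at 0.05 (adjusted p = 0.0192), while Emr1 itself passed at both. Only 2 macrophage and monocyte markers were left at 0.00236, too few for any split to pass. Dendritic cell markers had 5 of 12 decreased and 0 increased in the authors' deposited tables (adjusted p = 0.0181), with Ly6d 5.10-fold and Itgax 2.13-fold lower, and with the run error 0 remained at 0.00236 and 4 at 0.05 (adjusted p = 0.0401). Erythroid markers had 2 of 19 increased in the authors' deposited table, Car2 14.0-fold and Tfrc 2.40-fold (adjusted p = 0.633). Single members were listed for plasma cells, Irf4 at 2.98-fold higher, and for NK cells, Gzma at 2.42-fold lower, in the authors' deposited tables, with adjusted p of 1.0 and 0.530. None of the T cell, erythroid, plasma cell or NK cell genes passed with the run error at 0.00236, while 7 of the 8 T cell genes did at 0.05. No neutrophil or platelet marker was listed in the authors' deposited tables.

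**Figure D1:**
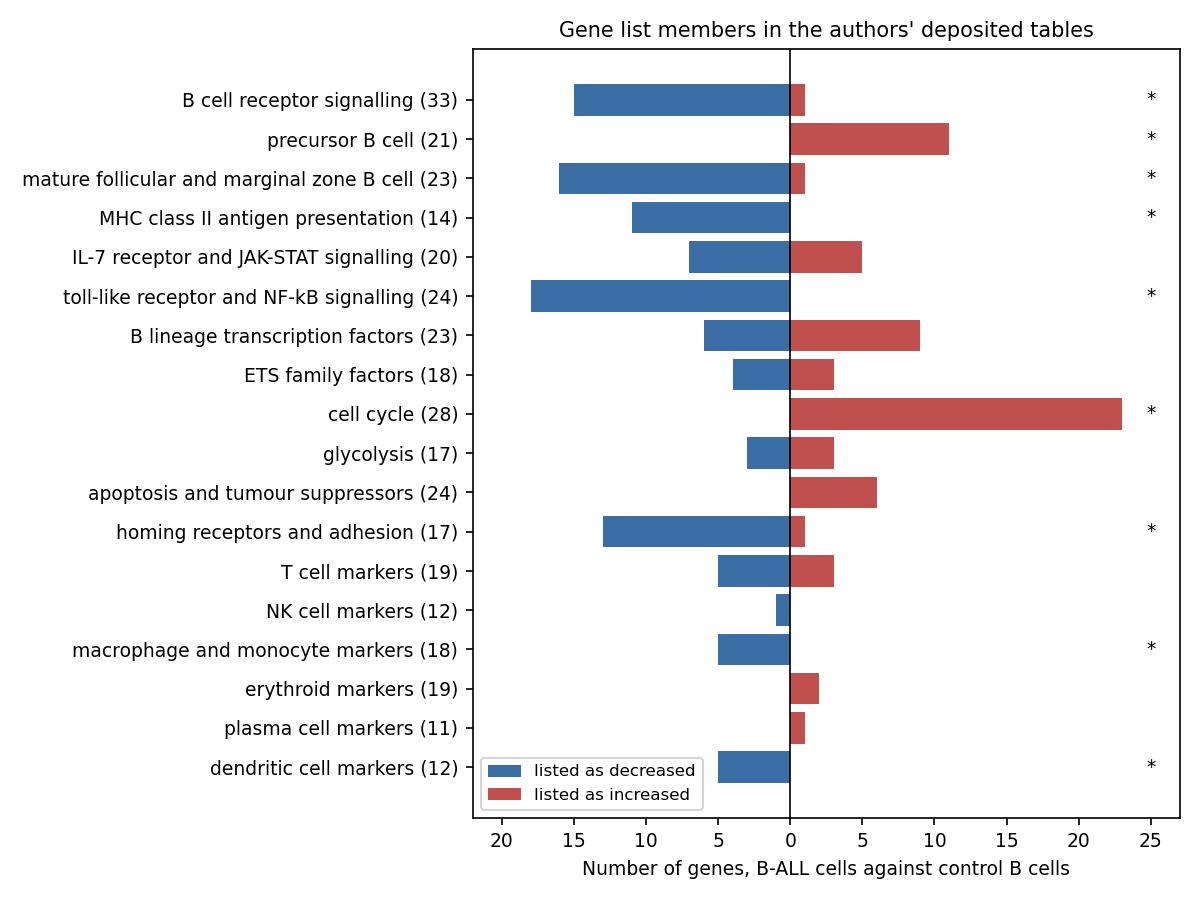
Bars count the members of each gene list that the authors' deposited tables gave as decreased (blue, left) or increased (red, right) in B-ALL against control cells, with the list's full size in parentheses. A star marks an adjusted p below 0.05 by Fisher's exact test, as for the 15 decreased genes of B cell receptor signalling and the 23 increased genes of cell cycle.

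Among the named rows of the value table, B-ALL cells differed from control cells by up to 6.76 on the log2 scale. After Ptprc, the largest decreases were those of Aim2, a sensor of cytosolic DNA, Kmo, an enzyme of the kynurenine pathway, Pgap1, which remodels GPI anchors, and Sell, the lymph node homing receptor L-selectin. By limma, Aim2 fell by 6.27 ± 0.31 (SE, adjusted p = 5.39e-05), Kmo fell by 6.03 ± 0.08 (adjusted p = 2.25e-07), Pgap1 fell by 5.36 ± 0.06 (adjusted p = 8.76e-08) and Sell fell by 5.35 ± 0.27 (adjusted p = 5.94e-05). Stat4, a cytokine signal transducer, fell by 4.62 ± 0.17 and Cd48, an adhesion receptor of lymphocytes, fell by 3.68 ± 0.09 (adjusted p = 1.27e-05 and 2.67e-06). Zap70 (row 6748662) rose by 5.38 ± 0.33, from 4.70 ± 0.43 (SD, n = 3) to 10.07 ± 0.25 (SD, n = 3; limma adjusted p = 0.000123). Cd244, an immune receptor that binds CD48, rose by 3.64 ± 0.18, Epb4.1l5 by 3.34 ± 0.10 and Pycr2, of proline synthesis, by 3.10 ± 0.09 (limma adjusted p = 5.39e-05, 6.49e-06 and 6.49e-06). These genes also passed with the runs of sample numbers as a block, with adjusted p of 0.0252 for Aim2, 0.00105 for Kmo and Pgap1, 0.0260 for Sell, 0.0426 for Zap70 and 0.00756 for Epb4.1l5. In the block fit the B-ALL side rests on B-ALL replicate 1 alone. That array lay near the mean of the other B-ALL arrays, with a median gap of 0.01. Similar differences with the block are therefore no separate support. Each SE above is from the fit without the block. With the block it was 0.58 for Aim2 and 0.19 for Epb4.1l5, and the median over all rows was 0.16 against 0.08 without it. Within the 1 run that held both groups, B-ALL minus control was -7.14 for Ptprc, -5.29 for Pgap1 and 4.86 for Zap70. All 4819 rows that limma called in this comparison had the same sign within that run, so the sign adds no separate support. Irs1, the insulin receptor substrate, and Sgol2, which protects centromeric cohesion, had log2 differences of 4.33 ± 0.33 and 3.40 ± 0.29, and their adjusted p of 0.000294 and 0.000496 became 0.0659 and 0.0941 with the block.

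**Figure D2:**
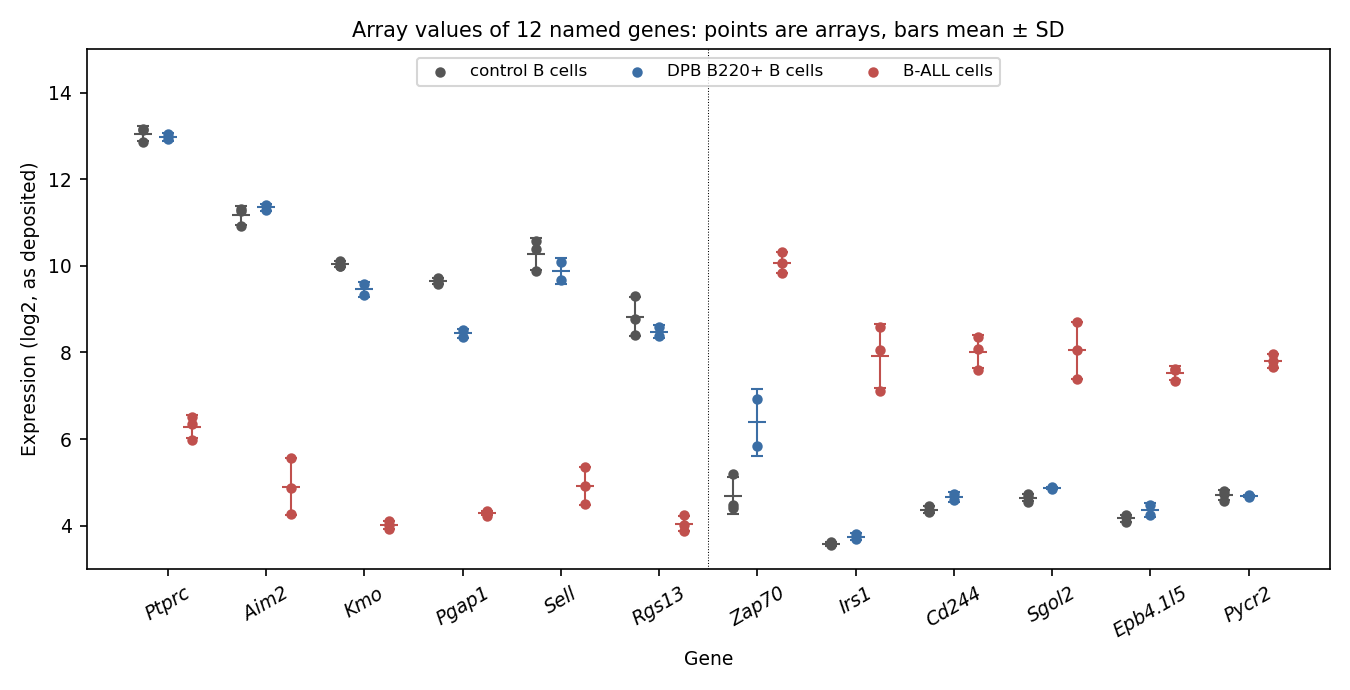
Points are the deposited log2 values of single arrays for the 6 named genes with the largest fall and the 6 with the largest rise in B-ALL against control, and bars give the mean and SD of each group (control n = 3, DPB B220+ n = 2, B-ALL n = 3). DPB B220+ arrays lie beside the control arrays for Ptprc, at 12.98 against 13.05, and between both other groups for Zap70, at 6.39.

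Over all 16380 rows, limma called 4819 in B-ALL against control at an adjusted p below 0.05, 2245 higher and 2574 lower, of which 678 and 904 reached 1.5-fold. Of these calls, 714 lay among the 1879 rows in the identifier range of the array controls, 455 higher and 259 lower. Among the 14501 other rows 1790 were called higher and 2315 lower, a smaller share than in the control range. With the runs of sample numbers as a block the calls were 150, 69 higher and 81 lower, all of them among the 4819. Quantile normalization gave 2738 higher and 2294 lower, and centring on array medians 2579 and 2280, so which direction had more calls depended on the scaling. Of the 164 named rows, 138 were called, 136 in the direction of the authors' deposited tables and 2, Csrp1 and Lypla1, against it (34 with the block). These rows were chosen by the authors on the same arrays, so that count is no independent evidence. Leaving out B-ALL replicate 1 gave 2083 calls and leaving out B-ALL replicate 2 gave 3138.

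DPB B220+ B cells differed from control cells in fewer called rows than B-ALL cells did. Unchanged groups simulated with run effects removed showed such a gap too, with 81.5 calls on average against 2185. The counts alone therefore do not show a smaller change. Among named genes, limma called 3 as lower, Pgap1, -1.21 ± 0.07 (SE; adjusted p = 0.00423), Cd48, -0.64 ± 0.10 (adjusted p = 0.0334), and Kmo, -0.59 ± 0.09 (adjusted p = 0.0353), all also lower in B-ALL. Gin1 was 0.61 ± 0.07 higher and Nrp2, a semaphorin receptor, 0.44 ± 0.05 higher (limma adjusted p = 0.0189 and 0.0186). For Nrp2 the authors' deposited table gave B-ALL as 3.07-fold lower than control, while the value table had a difference of -0.03 ± 0.04 (SE; limma adjusted p = 0.652). None of these 5 genes passed with the run block, where adjusted p was 0.362 for Pgap1 and 0.429 for the others. Pgap1 was lower in DPB B220+ within both runs that held the pair, by log2 differences of -1.07 and -1.32. Every one of the 344 rows called in this comparison kept its sign within both runs, so this adds no separate support. Across all rows the DPB B220+ minus control differences within the first run and within the next correlated at -0.093. Zap70 averaged 6.39 ± 0.77 (SD, n = 2) in DPB B220+ cells, 1.69 ± 0.37 (SE) above control, which did not pass (limma adjusted p = 0.0713). Over all rows limma called 344, 193 higher and 151 lower, and 3272 had an unadjusted p below 0.05. Of the 344, 68 lay in the identifier range of the array controls. With the run block limma called 0 (1372 at an unadjusted p below 0.05). Leaving out 1 array gave 29, 184 and 188 without control replicates 1, 2 and 3, 5 and 1 without DPB B220+ replicates 1 and 2, and 2, 51 and 62 without B-ALL replicates 1, 2 and 3.

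Many of the largest differences of B-ALL cells from control were also present against the DPB B220+ cells of the same mouse label. Both comparisons use the same 3 B-ALL arrays, so some likeness is built in. Sizes were not always alike, as Zap70 rose less than against control, and Ptpn14 and Ly96 fell more. Ptprc fell by 6.70 ± 0.17 (SE; limma adjusted p = 4.53e-06, and 0.00145 with the run block), Aim2 fell by 6.45 ± 0.35 and Kmo fell by 5.44 ± 0.09 (adjusted p = 0.000111 and 6.91e-07, and 0.0252 and 0.00145 with the block). Cd244 rose by 3.35 ± 0.20, Epb4.1l5 by 3.16 ± 0.11 and Pycr2 by 3.12 ± 0.11 (limma adjusted p = 0.000150, 1.93e-05 and 1.77e-05, and 0.0299, 0.00938 and 0.00960 with the block). Zap70 was 3.69 ± 0.37 higher in B-ALL (limma adjusted p = 0.00125), which did not pass with the block (0.106). With the block the B-ALL side again rests on B-ALL replicate 1 alone. Within the 1 run that held both groups, the differences were -6.93 for Ptprc and 4.21 for Zap70. All 3121 called rows had the same sign within that run, so here too the sign adds no separate support. Over all rows limma called 3121, 1479 higher and 1642 lower (1817 and 1583 after quantile normalization, 1543 and 1569 after centring on array medians), against 129 with the block, 47 higher and 82 lower, all among the 3121. Of the 3121, 526 lay in the identifier range of the array controls. Leaving out DPB B220+ replicate 1 gave 1217 calls, DPB B220+ replicate 2 gave 2023, B-ALL replicate 1 gave 1233 and B-ALL replicate 2 gave 2000.

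**Figure D3:**
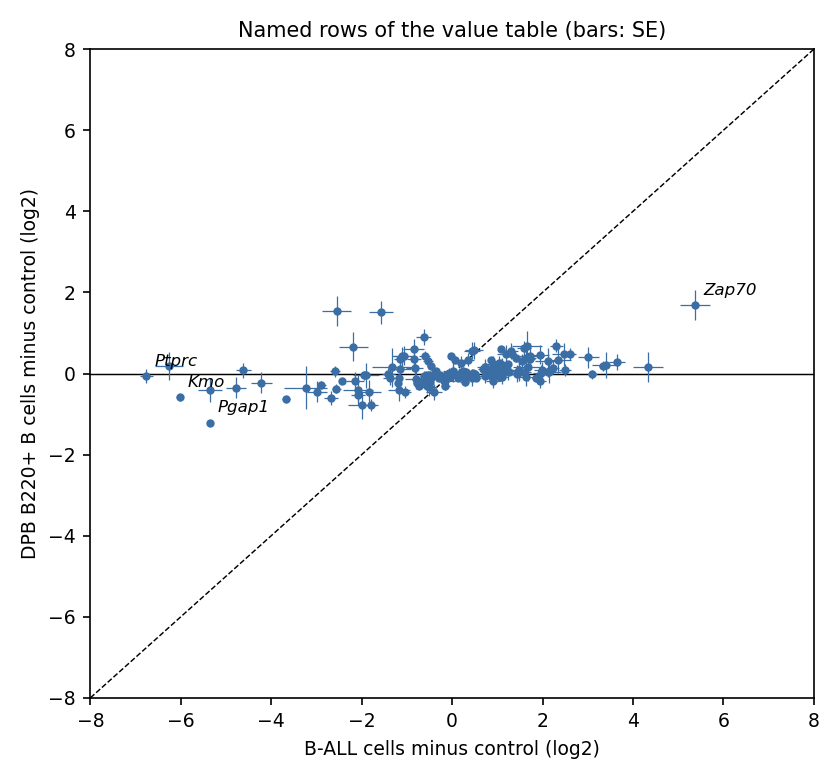
Each point is a named row of the value table, with the log2 difference of B-ALL from control on the x axis, that of DPB B220+ from control on the y axis, SE as bars, and a dashed line where both are equal. Of the 90 rows with a B-ALL difference of at least 1 in size, 89 had a DPB B220+ mean nearer to control than to B-ALL, among them 17 where DPB B220+ differed from control in the opposite direction.

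In most named genes that changed strongly in B-ALL the DPB B220+ difference was the smaller, and in some it was opposite in sign. In the 90 named rows that differed between B-ALL and control by at least 1 on the log2 scale, the DPB B220+ difference was a median of 0.0809 of the B-ALL difference, with quartiles of 0.0220 and 0.204. It was opposite in sign in 17 of the 90, and without regard to sign the median ratio was 0.106, with quartiles of 0.0541 and 0.245 and a highest value of 0.961. The largest opposite shifts, singled out after their values were seen, were those of Ptpn14, 1.54 ± 0.36 (SE) in DPB B220+ against -2.56 in B-ALL, and Ly96, 1.51 ± 0.29 against -1.57, and neither passed in DPB B220+ against control (limma adjusted p = 0.0832 and 0.0541). These rows were chosen for a large B-ALL difference, which by itself lowers the ratio. Over all 16380 rows the median size of the difference from control was 0.11 for DPB B220+ and 0.16 for B-ALL. Over all rows, 214 were called in the same direction against control in both DPB populations and 38 in opposite directions, and with the run block 0 were shared. The shared count was 17, 121 and 121 without control replicates 1, 2 and 3, 2 and 0 without DPB B220+ replicates 1 and 2, and 1, 27 and 33 without B-ALL replicates 1, 2 and 3. Both comparisons use the same 3 control arrays, and simulated unchanged groups against them shared 0 calls on average, or 45.9 (highest 87) where run effects had been removed, while independent lists of these sizes would share 50.2. The simulations with run effects removed called 81.5 and 2185 rows on average, against 344 and 4819 here. Their shared calls thus come from shorter lists, and the gap from 214 does not by itself show an excess. The log2 differences correlated at 0.32 across rows, against 0.45 for simulated unchanged groups, or 0.35 with run effects removed, and their covariance was 0.0421 against 0.0111 simulated, or 0.0143 with run effects removed. The 3 controls are too few to be split, so part of any excess, in shared calls or in covariance, may come from sharing them.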

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

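The tests on array controls, on T cell markers and on simulated groups in this part were chosen after the results they weigh were seen.

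The authors' deposited tables listed 737 rows annotated as array controls as changed, data outside the gene comparisons. A shift in scale between the arrays of both groups would move them all the same way, yet 454 were decreased and 283 increased in the authors' deposited tables, which argues against such a shift as the whole cause. Among the negative controls 403 were decreased and 136 increased in the authors' deposited tables, and among the positive controls 51 and 147. In the value table, listed negative controls had a median B-ALL minus control difference of -0.62 and listed positive controls one of 1.09. These had been picked as changed. All 1879 rows of the control identifier range had a median of 0.08, and the 1645 not listed one of 0.10. A shift that depends on signal level stays open, as does signal of transcripts at these probes. No biological explanation was tested.

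In the value table, 38 rows were called against control in opposite directions in the DPB populations, 27 higher in DPB B220+ and lower in B-ALL and 11 the other way. The difference between both populations was itself called for all 38 by limma, and for 11 with the run block, but 0 of the 38 kept their limma call in DPB B220+ against control with the block. Simulated unchanged groups with run effects removed gave 8.06 such rows on average and 16 at most. They also had fewer calls, 81.5 and 2185 on average against 344 and 4819, so these counts do not share a base. No row among the 38 could be named.

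Zap70, Lck and Lat were increased while Cd3e, Cd4, Cd8a, Cd5 and Icos were decreased in B-ALL in the authors' deposited tables. T cells in the B220-negative sort would raise all of their abundant transcripts, yet 5 of the 8 listed T cell markers were decreased, and Cd3e was 4.90-fold lower in the authors' deposited table, which argues against T cells as the source of the rise. Fewer T cells in the B220-negative sort than in the control sort would lower all of them, yet 3 were increased, so this could account for no more than the 5 decreases, for which it stays open. With the run error none of the 8 passed at 0.00236 and 7 did at 0.05, with Cd8a as the exception. The value table also had Zap70 higher in B-ALL, at 10.07 against 4.70, which passed with the run block, where B-ALL rests on replicate 1 alone. Transcription of Zap70, Lck and Lat by the leukaemia cells themselves stays open and was not tested.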

How the results depend on the processing

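The block at 1.5-fold, the removal of the control identifier range and every alternative on the authors' deposited tables were chosen after the data were seen. The direction of all 53 named gene results was kept in all 901 values under 17 alternatives, and 32 passed the threshold under every one. These results were chosen for large differences with no overlap between the arrays of both groups. Leaving out an array could therefore not turn their direction, and the kept direction is no separate support. Several genes recur across comparisons. With the runs as a fixed block 21 of the 53 results no longer passed, and 47 passed under every other alternative. With that block the counts were 0 for DPB B220+ against control by limma (1372 at an unadjusted p below 0.05), 150 for B-ALL against control, 129 for B-ALL against DPB B220+ and 0 shared (from 344, 4819, 3121 and 214). Fewer residual degrees of freedom are part of its construction, as is the reliance of both B-ALL comparisons on B-ALL replicate 1 alone. As a random block, with a consensus correlation of -0.488, the runs gave 780, 12108 and, shared, 582. Array weights gave 8317 for B-ALL against control, 5783 against DPB B220+ and 330 shared. With 2 groups in the fit, DPB B220+ against control had 0 calls by limma (2167 at an unadjusted p below 0.05, and 402 by the methods' ANOVA after Benjamini-Hochberg on all arrays) and 0 were shared. The methods' ANOVA at an unadjusted p below 0.05 and 1.5-fold gave 1659 for B-ALL against control and 1419 against DPB B220+, and limma at the same limits 1792 and 1556. A 1.5-fold minimum on adjusted calls gave 124 for DPB B220+ against control, 1582 and 1273 for B-ALL, and 64 shared. With the block at 1.5-fold and unadjusted p, the B-ALL counts were 1224 and 1144, with 125 shared. A fold minimum lowers counts by construction. For the random block, array weights and the fit on 2 groups the cause was not tested. Leaving out 1 array gave 1 to 188 for DPB B220+ against control, 2083 to 4650 for B-ALL against control, 1217 to 3568 against DPB B220+, and 0 to 121 shared. DPB B220+ against control had 29, 184 and 188 without control replicates 1, 2 and 3, 5 and 1 without DPB B220+ replicates 1 and 2, and 2, 51 and 62 without B-ALL replicates 1, 2 and 3. Shared calls were 17, 121 and 121 without control replicates 1, 2 and 3, 2 and 0 without DPB B220+ replicates 1 and 2, and 1, 27 and 33 without B-ALL replicates 1, 2 and 3. B-ALL against control had 2083 and 3138 without B-ALL replicates 1 and 2. B-ALL against DPB B220+ had 1217 and 2023 without DPB B220+ replicates 1 and 2, and 1233 and 2000 without B-ALL replicates 1 and 2. A lone DPB B220+ array was assumed to vary like the other groups. Quantile normalization, median centring, trended variances, removal of dim rows or of the control identifier range kept every count within 1.5 times, though the balance of higher and lower calls in B-ALL against control turned under both scalings (2738 and 2294, 2579 and 2280) and against DPB B220+ under quantile normalization (1817 and 1583).

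In the authors' deposited tables, with the run error 315 decreased and 303 increased genes remained of 1291 and 2082 at the limit of 0.00236, and 1141 and 1846 at 0.05, the limit named in the methods. Of 65 list results under alternatives 58 kept their side of the threshold. With the run error at 0.05 all 17 lists with a member left kept theirs, which says little because that limit removed few genes. At 0.00236 the adjusted p was 0.218 for precursor B cells, 0.390 for cell cycle, 0.160 for homing and 0.649 for macrophages, and dendritic cell markers had no member left. At a fold of at least 2 it was 0.284 for macrophages and 0.284 for dendritic cells, and at a contrast p below 0.0005 it was 0.596 for dendritic cells. Fewer genes entered each of these tests. With the 3 precursor, 2 cell cycle and 2 macrophage genes left at 0.00236, no split could have passed. Camera, its estimated correlation, fry and their scalings were not run. No paired analysis was possible because the labels pair no replicates across groups, and the runs of title numbers entered as a block instead. The median level of rows, 4.11 to 4.18, leaves small changes of dim rows near background unresolved.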

Other observations

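The tests and gene families in this part were chosen after the results were seen. As for the lists, Fisher's exact test treats genes as independent, so its p-values may be too small. Of 70 symbol stems with at least 6 listed genes, 10 had a split into increased and decreased genes in the authors' deposited tables that differed from that of all 3373 listed genes (Fisher's exact test, Benjamini-Hochberg adjustment), and 60 did not pass. Because 2082 listed genes were increased, a wholly increased stem needs more members to pass than a wholly decreased one. All 10 Nup, all 9 Mrps and all 9 Psmd genes were increased without passing (adjusted p = 0.0911 each, Fisher's exact test). All 8 listed Gimap genes, small GTPases of lymphocytes, were decreased in the authors' deposited table (adjusted p = 0.0106), led by Gimap4 at 86.3-fold and Gimap3 at 31.2-fold lower. All 6 listed Gbp genes, interferon-induced guanylate binding proteins, were decreased in the authors' deposited table (adjusted p = 0.0243), with Gbp3 15.5-fold and Gbp5 7.48-fold lower. Genes of the stem Il, which are interleukins, receptor chains and the amino acid oxidase gene Il4i1, had 14 decreased and 2 increased in the authors' deposited tables (adjusted p = 0.00243). Il21r was 100-fold lower, Il10ra 67.6-fold lower and Il4ra 39.6-fold lower in the authors' deposited table, while Il7r and Il33 were higher. All 14 listed Mrpl genes, of the large subunit of the mitochondrial ribosome, were increased in the authors' deposited table (adjusted p = 0.0212), by up to 3.41-fold for Mrpl13. With the run error, 3 Gimap, 3 Gbp, 9 Il and 2 Mrpl genes passed, and Il7r, Il33 and Mrpl13 did not. These counts are at the limit of 0.00236, and at a run-error p below 0.05 they were 7 of 8, 5 of 6, 15 of 16 and 12 of 14. The stem with the lowest adjusted p, Cd, joins genes of unrelated proteins, with 28 of 34 decreased in the authors' deposited tables (adjusted p = 1.56e-05) and 12 passing with the run error (30 at 0.05). Snx had 9 of 10 decreased (adjusted p = 0.0199, 0 passing with the run error and 10 at 0.05) and Cyp 7 of 8 (adjusted p = 0.0444, 4 passing and 5 at 0.05) in the authors' deposited tables. The stems Ly and S, which join several kinds of genes, each had 6 of 6 decreased in the authors' deposited table (adjusted p = 0.0243, 1 passing each, and 6 and 3 at 0.05). Slc was split, 28 increased and 37 decreased in the authors' deposited tables (adjusted p = 0.0243, 11 passing and 58 at 0.05).

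The largest changes in the authors' deposited tables included genes of no fixed list. Ms4a4c was 314-fold lower and Stap1, a B cell adaptor, 202-fold lower in the authors' deposited table. F13a1, a coagulation factor subunit, was 62.6-fold higher, Gfra1, a receptor of GDNF, 57.3-fold higher and Lgr5, a receptor of R-spondins, 46.4-fold higher in the authors' deposited table. Ms4a4c and F13a1 passed with the run error, and Stap1, Gfra1 and Lgr5 did at 0.05 but not at 0.00236. Both immunoglobulin segment genes listed, Igk-V19-20 and Igh-VJ558, were decreased in the authors' deposited table, and with the run error neither passed at 0.00236 and Igh-VJ558 alone passed at 0.05.

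Deviations of the arrays from their group means nearly cancelled within the runs of title numbers. Squared run sums were 0.0950 of the squared deviations, against at least 1.87 in 50 simulations of independent arrays. Control replicate 1 and DPB B220+ replicate 1, of 1 run, deviated with a correlation of -0.965 across rows, where independent arrays would have one near 0, which argues against independence. The median gap of B-ALL replicate 1 from the mean of the other B-ALL arrays was 0.01, against 0.11 between those arrays. A candidate explanation is a batch correction that kept the group means, which predicts a ratio below all simulated values, as found here. The series' design text states that batch effects were removed with ComBat. Whether its batches were these runs is not given in the sources used here.

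In B-ALL against control 4819 rows were called, and the highest of the other splits of these 6 arrays gave 0. Only 10 splits exist and 1 of them, the real one, reached that count, too few for a share under 0.05.

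A hypothesis for the closeness of DPB B220+ cells to control in named genes changed in B-ALL is that they kept Sfpi1 transcript. The sums of squares in the authors' deposited table allow a pair of values for Sfpi1 in DPB B220+ minus control, -0.11 or one near the -6.11 of B-ALL minus control, so whether Sfpi1 was kept cannot be told apart from its loss; the row is not among those of the value table used here. For Ptprc the same sums allow -0.16 or -6.61, and its measured value was -0.07. For 2638 of 3373 genes these sums place the DPB B220+ mean at least 0.5 of the way from the midpoint to either other group. For 1019 of them it lay beyond control or beyond B-ALL and not between both.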
